A study of Homo sapiens with 6 samples.

How the data were processed

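RNA was measured in 6 libraries of U-2OS cells, a human osteosarcoma line, all treated with actinomycin D, an inhibitor of transcription. Per the labels, 3 libraries came from cells given a control siRNA (siCtrl) and 3 from cells given an siRNA against SFPQ (siSFPQ). The dose and duration of actinomycin D were not given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol, selected for poly(A) tails and made into stranded libraries. The labels do not say that the libraries came from separate cultures. The p-values of the fits therefore rest only on the spread between these samples, pooled across genes, which may be technical. They name no batch.

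The deposited values were raw read counts per gene, whole numbers with no normalisation, in 1 table of 35036 genes with their coordinates and exonic lengths. The aligner, counting program, annotation and genome build were not given in the sources used here. Of the 13886 gene identifiers shared with GENCODE release 29 on GRCh38, 13886 lay on the same chromosome and 13874 overlapped the position there, so coordinates are given as the table lists them and read as GRCh38. Of those 13886 genes, 50 were protein-coding in that release, so the table is one of non-coding genes. SFPQ, NONO, PSPC1 and SRSF1 were not analysed here. The table's totals of 1298658 to 1599566 counts per library are therefore part of each library and not its sequencing depth. CPM here is relative to the table's own counts after TMM scaling.

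The counting did not separate overlapping genes. MALAT1 on the plus strand and TALAM1 on the minus strand over it held 72563 and 72552 counts in total, and 3 overlapping pairs on opposite strands agreed within 1%. Reads from overlapping genes on either strand cannot be told apart, and 69.1% of all counts lay in genes overlapping exons of coding genes. Overlap was taken from GENCODE 29 exons for 3775 tested genes and from the listed span for the other 2550, whose identifiers that release lacks. The listed exonic length exceeded the listed span for 342 genes, NEAT1, MALAT1 (10468 over 8911 bases) and DANCR (10179 over 9359) among them. The coordinates given for such genes may not hold all that was counted.

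Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, robust quasi-likelihood fits with the group as the sole term, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The filter left 6325 genes; 14030 had no count and 14681 more had too few, holding 1.76% of counts. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 where at least 5 members were tested, with an estimated correlation and fry as alternatives. The lists, the design, the named-gene rule and most alternatives were fixed before the data were examined. Of the fixed lists, only the snoRNA host genes and the nuclear long non-coding RNAs had enough members in the table to test, and the paraspeckle list had NEAT1 alone. The other lists are of coding genes. They were carried over to the non-coding genes that overlap exons of their members, a step added after the data were examined.

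Named genes were NEAT1; the 10 largest increases and decreases among called genes with a mean of at least 5 CPM and groups that did not overlap; the 4 members with the smallest adjusted p of each called list and 2 of each other list; and the 4 most abundant called genes in each direction. One gene that this rule takes is not reported here. Other members of lists are named as examples chosen after their values were seen. Gene span was related to fold change by Spearman's rho across genes, which are not independent replicates. Span was the listed one, widened to the GENCODE 29 coordinates for genes in that release, so that NEAT1 spanned 22767 bases. An adjustment for GC content was void, because only those 3775 of the 6325 tested genes had exons in the reference.

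Replicates were compared before averaging. Chi-square statistics per degree of freedom between libraries of 1 group were 1.24 to 1.40 with p of at most 2.0e-36, so no pair was a duplicate. Pearson's r of log2 CPM across genes was 0.981 to 0.984 within groups and 0.936 to 0.939 between them. The fit was tested on simulated counts for the same comparison over 6106 genes: of 100 genes changed by a log2 fold of 1 it recovered 82, of 100 changed by 0.5 it recovered 42, and it called 5 unchanged genes. All simulated genes had 1 dispersion, and the changed ones were planted only above a minimum mean count. The simulation therefore did not test the fit with spread that differs between genes. Nor did it test one with as many changes as the data, where 48.4% of genes were called. Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter and a stricter filter (at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a replicate block, and leaving out each library. Added after the data were examined were scaling by plain library totals, fits without genes overlapping coding exons, with 1 gene per overlapping cluster, with scaling from non-overlapping genes, and DESeq2 on the filtered genes.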

Results

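Poly(A)-selected RNA was counted over non-coding genes in actinomycin D-treated U-2OS osteosarcoma cells, 3 libraries with a control siRNA and 3 with an siRNA against SFPQ. SFPQ is an RNA-binding protein of paraspeckles, nuclear bodies built on the NEAT1 RNA. Total counts in the table ranged from 1385532 to 1533974 in siCtrl and from 1298658 to 1599566 in siSFPQ. SFPQ itself was not analysed here, so the knockdown was not checked on its target and the groups rest on the labels.

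The first comparison asked which non-coding genes differed between siSFPQ and siCtrl cells under actinomycin D. Counts of the paraspeckle gene NEAT1 (ENSG00000245532, chromosome 11, 65422774 to 65426385 as listed) fell from 16029 ± 705 CPM in siCtrl to 10668 ± 621 CPM in siSFPQ (SD, n = 3 each). They are counts per gene in poly(A)-selected RNA and do not separate the isoforms of NEAT1, so the scaffold form was not measured apart. MALAT1, an abundant nuclear RNA of speckles (ENSG00000251562, chromosome 11, 65497606 to 65506516), fell from 11974 ± 503 to 4968 ± 46.7 CPM. DANCR (ENSG00000226950, chromosome 4, 52712325 to 52721683) rose from 1905 ± 40.0 to 3630 ± 102 CPM. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were -0.59 ± 0.04 (SE, adjusted p = 9.6e-49) for NEAT1, -1.27 ± 0.04 (adjusted p = 7.3e-204) for MALAT1 and 0.93 ± 0.05 (adjusted p = 2.2e-91) for DANCR. MALAT1 counts cannot be told from those of its antisense gene TALAM1. How much of the NEAT1 and MALAT1 RNA the poly(A) selection captured was not measured, so both falls are falls in captured counts.

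**Figure D1:**
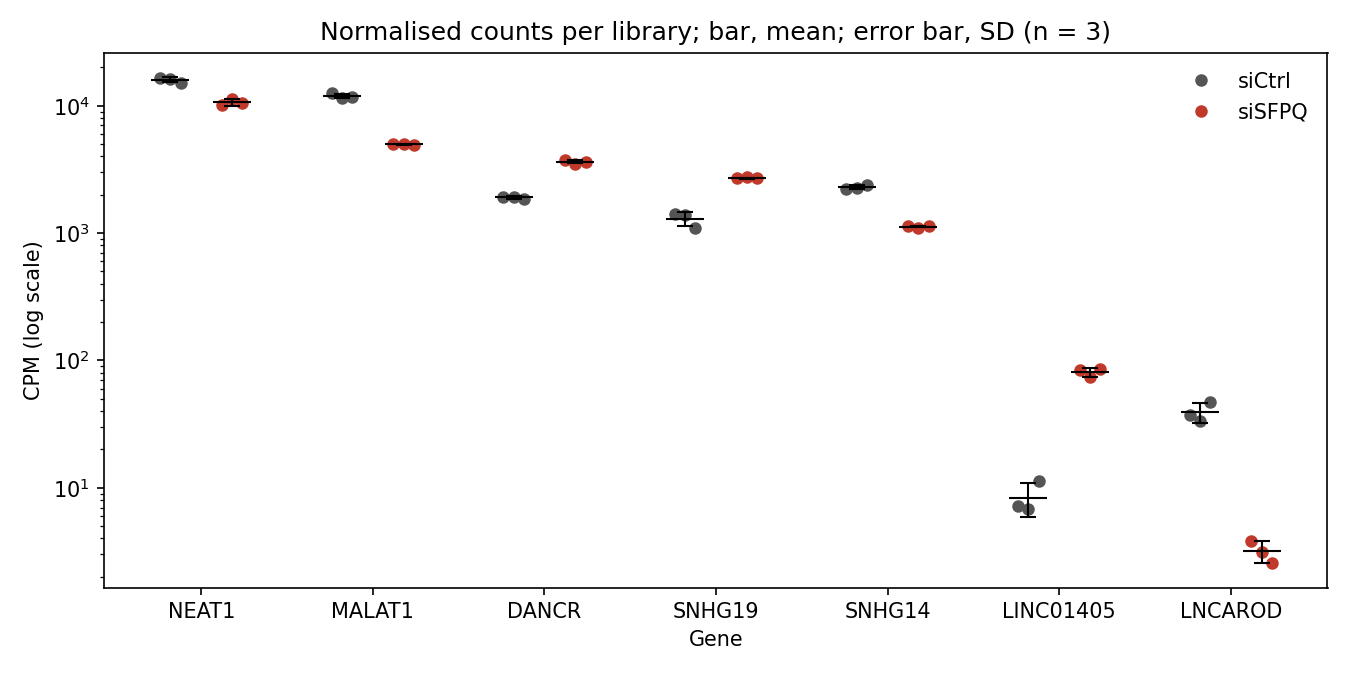
CPM on a log scale for 7 named genes, with a point per library (grey, siCtrl; red, siSFPQ), a bar at the mean and an error bar of 1 SD (n = 3). For each of these genes the 3 siSFPQ libraries lay on one side of the 3 siCtrl libraries, as for NEAT1 at 10193 to 11371 against 15221 to 16519 CPM. The rule that named LINC01405 and LNCAROD required this separation. The others except NEAT1 were named for the smallest adjusted p of their lists.

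Of 6325 genes tested with edgeR, 1547 were higher and 1516 lower in siSFPQ at an adjusted p under 0.05, and 434 and 340 of these changed by a log2 fold of at least 1. The groups did not overlap for 54.0% of tested genes, where chance gives 10%. Among the 2955 genes without overlap with coding exons, 745 were higher and 727 lower. Among the 3370 with such overlap, 802 were higher and 789 lower. DESeq2 called fewer genes, 858 higher and 904 lower.

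The largest increase with ample counts was that of LINC01405, a long intergenic RNA on chromosome 12 (ENSG00000185847, 110934267 to 110973868), from 8.38 ± 2.46 to 81.2 ± 6.67 CPM (SD, n = 3; log2 fold change 3.27). ENSG00000302960, antisense to the stress-induced pseudokinase gene TRIB3, had 2 counts over the siCtrl libraries and 48 over the siSFPQ libraries, a ratio of 22.6 with a 95% counting interval of 5.94 to 192. ENSG00000287296, which overlaps the immediate early gene IER2, rose by 3.23 on the log2 scale, while the more abundant ENSG00000267598 over the same gene, at 195 CPM in both groups, was not called (log2 fold change 0.01, edgeR, adjusted p = 0.93). ENSG00000303816, over BICD2, rose by 2.73. Further increases were 2.97 for ENSG00000308838, 2.93 for LINC00602, 2.90 for ENSG00000287609, 2.83 for ENSG00000178107, 2.72 for ENSG00000300428 and 2.70 for ENSG00000310131. LNCAROD (ENSG00000231131, chromosome 10, 52445975 to 52755432) fell furthest, from 39.2 ± 7.15 to 3.17 ± 0.618 CPM, a log2 fold change of -3.60. ENSG00000303477, next to a ribosomal RNA gene unit on chromosome 21 in the RefSeq annotation of GRCh38, had counts of 13, 12 and 17 in siCtrl and of 1, 4 and 1 in siSFPQ (-2.81). Its counterpart beside another copy of the unit, ENSG00000295792, was not called, with 14.6 ± 3.27 CPM in siCtrl and 20.4 ± 6.05 CPM in siSFPQ (edgeR, adjusted p = 0.080). How reads were assigned between copies of the unit was not given, so the fall at 1 copy may not hold for the copies together. HLA-DQB1-AS1, over an HLA class II gene, changed by -2.42 and ENSG00000303304, over the acute-phase gene SAA1, by -2.38. The remaining decreases were -3.10 for ENSG00000297167, -2.95 for ENSG00000297294 over DUSP9, -2.69 for ENSG00000294922, -2.65 for ENSG00000305870 over PTPRM, -2.44 for ENSG00000291166 and -2.34 for ENSG00000287188 over ANXA10.

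The most abundant changed genes mostly lay over exons of highly expressed coding genes, whose reads they cannot be told from. ENSG00000269968, over the glycolytic gene GAPDH, took 5.47% to 5.51% of counts in siCtrl and 4.37% to 4.58% in siSFPQ and had a log2 fold change of -0.36. TUBA1B-AS1, over an alpha-tubulin gene, changed by -0.47 and ENSG00000303314, over the pyruvate kinase gene PKM, by -0.70. ENSG00000264772, over the translation initiation factor gene EIF4A1, rose by 0.51 and MIF-AS1, over the cytokine gene MIF, by 0.19. CERNA3 had a log2 fold change of 0.10 (edgeR, adjusted p = 0.019), and its call was lost without siCtrl replicate 2 (adjusted p = 0.064), siCtrl replicate 3 (0.229) or siSFPQ replicate 3 (0.104), with no filter (0.132) and among genes without coding exon overlap alone (0.053), over a range of 6.0e-05 to 0.229 among all alternatives.

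The second comparison asked whether gene lists moved together. Among snoRNA host genes, whose introns carry small nucleolar RNAs that guide ribosomal RNA modification, 18 of 24 tested members rose, 3 fell and 3 were not called, and the same 21 passed when adjusted over the list alone. SNHG19 (ENSG00000260260, chromosome 16, 2151103 to 2155358) rose from 1295 ± 166 to 2706 ± 26.7 CPM (SD, n = 3), SNHG8 by 0.80 and GAS5 by 0.52 on the log2 scale. SNHG4 rose by 1.18 but shares exons with MATR3. SNHG14, the long host at the imprinted SNRPN and UBE3A locus, whose exons it overlaps, fell from 2292 ± 81.5 to 1125 ± 17.1 CPM, and SNHG17 and SNHG7 had log2 fold changes of -0.30 and -0.14. With plain library totals 19 members were higher and 1 lower. The list's median log2 fold change was 0.39, with a camera adjusted p = 2.3e-10 (limma) at the preset correlation and an adjusted p = 0.026 with an estimated correlation.

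Members of the fixed list named nuclear long non-coding RNAs went both ways: of 18 tested, 8 rose, 7 fell and 3 were not called. Adjusted over the list alone the same numbers passed. The name is that of the list, and where in the cell its members lay was not measured. Besides MALAT1 and DANCR, OIP5-AS1 changed by -0.84 and MIR22HG, the host of a microRNA, by -1.02. JPX rose by 0.57 and NORAD, a cytoplasmic RNA that binds Pumilio proteins, by 0.25. The median was -0.02, and camera (limma) gave an adjusted p = 0.82 at the preset correlation and 0.82 with an estimated one.

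**Figure D2:**
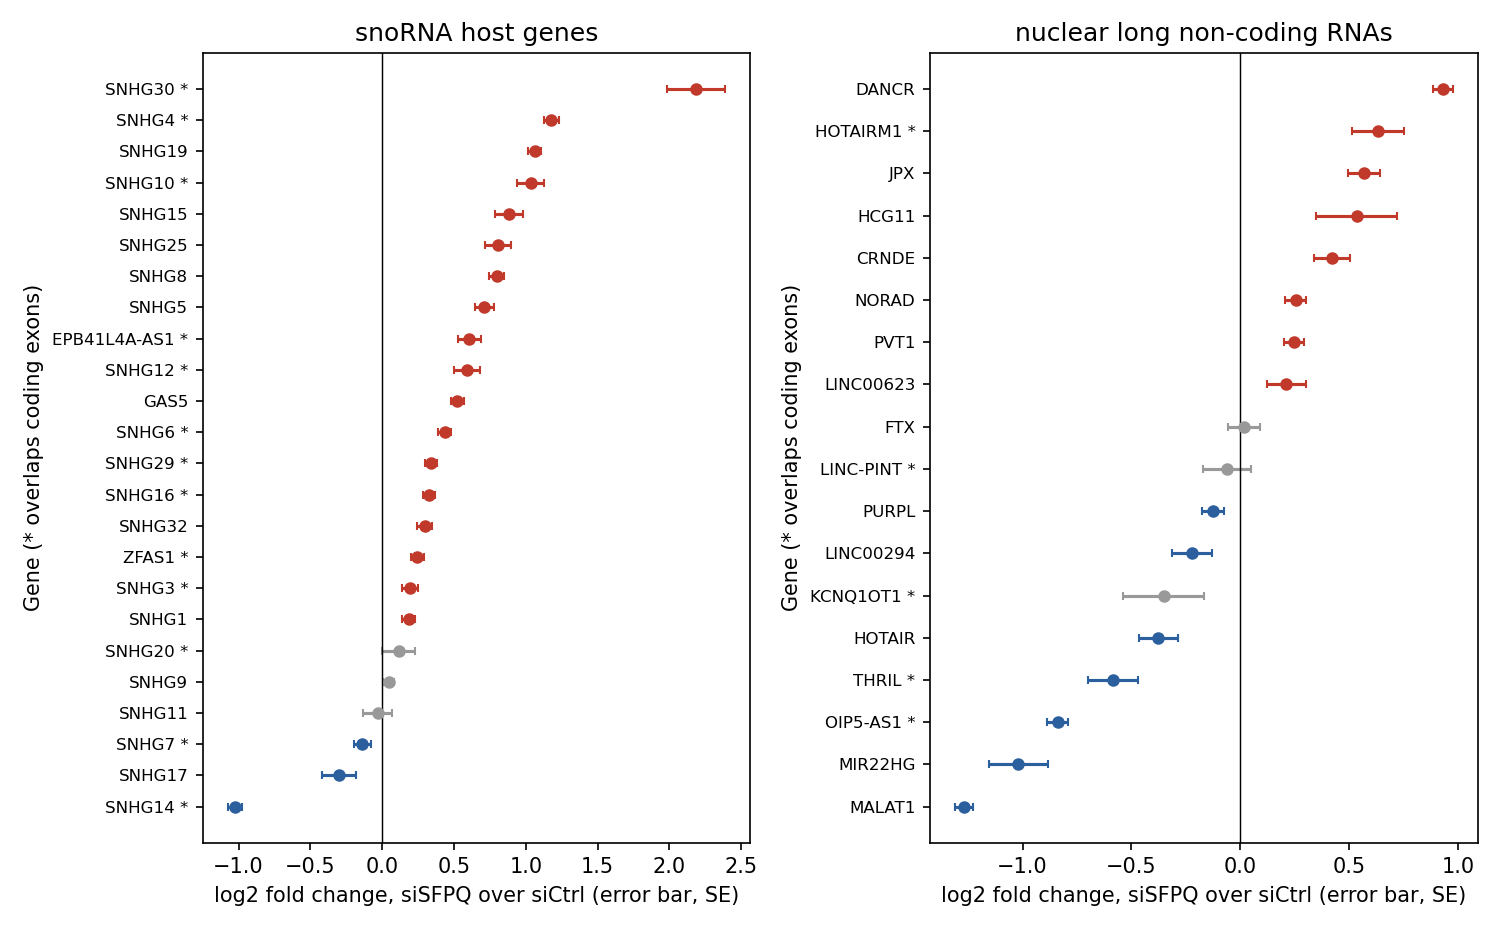
Log2 fold change of siSFPQ over siCtrl with its SE for the members of both tested lists (red, higher; blue, lower; grey, not called), an asterisk marking overlap with coding exons. Of the snoRNA host genes 18 lay to the right as higher, and of the list named nuclear long non-coding RNAs 8 were higher and 7 lower.

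Non-coding genes over exons of coding genes were then grouped by the coding lists, after the data were examined. All 5 over unfolded protein response genes fell, such as HYOU1-AS1 (-0.38) and ENSG00000267458 over the chaperone gene CALR (-0.28). Over glycolysis and hypoxia genes 10 of 18 fell, including ENO1-AS1 (-0.44) and ALDOC-AS1 (-0.98), and 3 rose. Of these 3, SLC2A1-DT and ENSG00000283973 overlap each other at the glucose uptake gene SLC2A1 and may share reads. The other was HK2-DT at the hexokinase gene HK2 (1.06). The more abundant ENSG00000309281 over HK2 was not called (-0.15, edgeR, adjusted p = 0.20). Over extracellular matrix and osteogenic genes 9 of 15 fell and 1 rose, with COL4A2-AS1 at -0.90 and LOXL2-AS1 at -0.79. Over nuclear oxidative phosphorylation genes 6 of 12 fell, including LINC00649 at ATP5PO (-0.93). Over cytosolic ribosomal protein genes 16 of 28 rose and 1 fell, over ribosome biogenesis genes 7 of 13 rose and 1 fell, with NOP14-AS1 at 0.59, and over integrated stress response genes 9 of 19 rose and 2 fell, with CARS1-AS1 at 0.53. Camera (limma) at the preset correlation called these 7 of 23 groups, with adjusted p from 0.0010 to 0.026, and 0 with an estimated correlation, with adjusted p = 0.22 to 0.48. These counts can hold reads of the coding genes, most of them on the other strand, so they do not separate the non-coding gene from its partner.

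**Figure D3:**
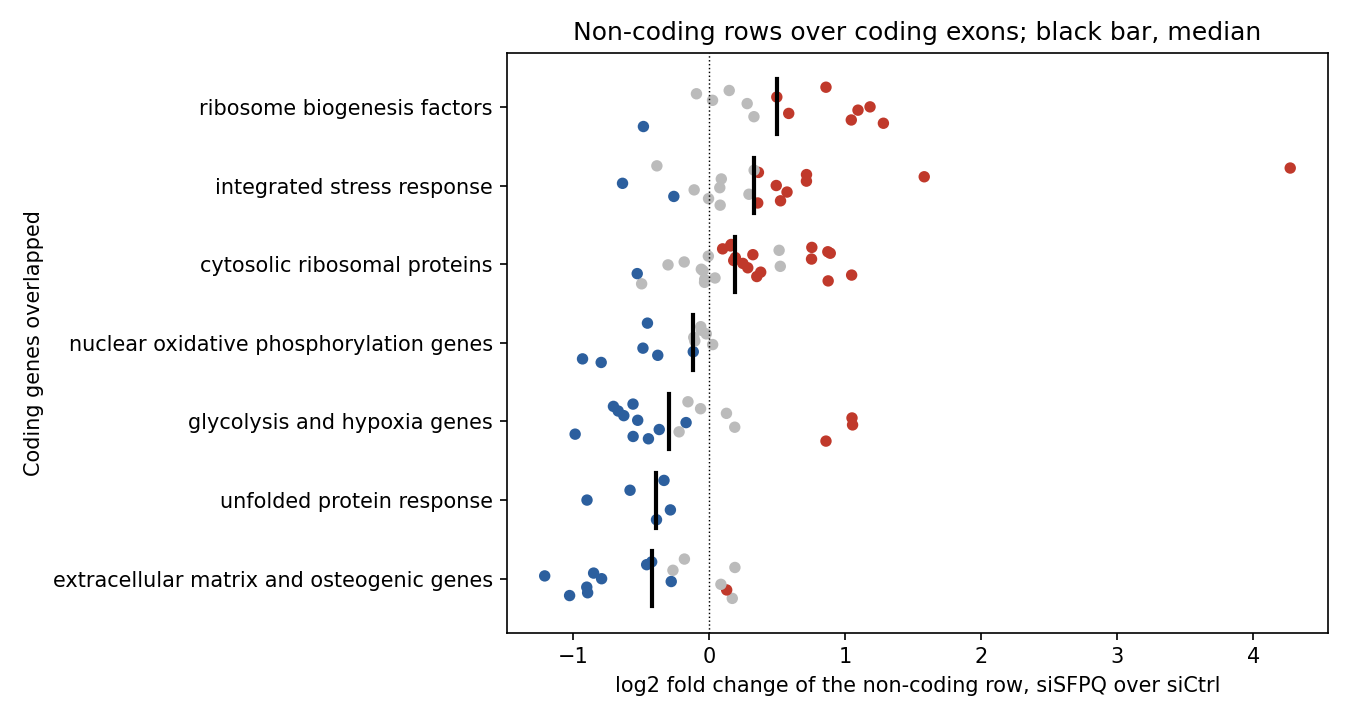
Log2 fold change of siSFPQ over siCtrl for non-coding genes that overlap exons of coding genes, by list, for the 7 lists called at the preset correlation (red, higher; blue, lower; grey, not called; black bar, median). The medians ran from -0.42 over extracellular matrix genes to 0.50 over ribosome biogenesis genes.

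The last comparison asked whether change followed gene length. The 701 non-coding genes spanning over 100 kb had a median log2 fold change of -0.11 and the other 5624 one of 0.03, a difference of -0.13. Across genes, which are not independent replicates, Spearman's rho of span with log2 fold change was -0.048. Over the 9 pairs of single libraries the difference ran from -0.17 to -0.08, and with no low-count filter it was -0.02. After adjustment for exonic length the difference was -0.08 and rho -0.028.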

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

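Plain library totals, DESeq2 on the filtered genes, the settings based on overlap (genes without coding exon overlap alone, scaling from those genes, 1 gene per overlapping cluster) and all settings for the coding-locus groups were chosen after the data were examined. RLE and upper-quartile scaling, both filters, limma-voom and leaving out each library kept the counts of higher and lower genes within 1.5 times, at 1382 to 1464 higher and 1378 to 1440 lower with a library left out. DESeq2 gave 858 higher and 904 lower, and 1013 and 1074 on the edgeR-filtered genes, so the filter accounts for part of the difference from edgeR; the cause of the rest was not tested. Plain library totals gave 1762 higher and 1304 lower, so that 57.5% of calls were higher. A log2 fold of at least 1 left 434 and 340 genes. Genes without coding exon overlap alone gave 736 and 721, since fewer genes were tested. Replicate numbers did not pair the samples: correlations of deviations between libraries of the same number were -0.005, 0.001 and 0.010, and the replicate block gave 1535 higher and 1515 lower and changed no list call. The snoRNA host list stayed called under every alternative run, with adjusted p from 5.4e-17 to 0.026, and fry, which does not compare a list with other genes, called 2 lists. The camera test already used voom values, so limma-voom could not change it. The coding-locus groups called numbered 0 with an estimated correlation, 17 with fry and 10 with no filter, where paraspeckle components, p53 targets and interferon-stimulated genes gained a call; the cause was not tested. Spearman's rho of span was -0.026 without a filter, -0.033 with the stricter filter and -0.028 after adjustment for exonic length, and the difference of medians was -0.020 without a filter and -0.078 after that adjustment; the cause was not tested. Of 593 values of the named genes under alternatives, 588 kept direction and call, 5 lost the call, all for CERNA3, and 0 reversed. Removing mitochondrial genes was not run, having none to remove, and SFPQ's own fold change was not analysed here. Low counts limit the least abundant genes, such as ENSG00000302960.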

Other observations

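The test of hosts without coding exon overlap was chosen only after the result was seen, as were the classes by name. Genes named as divergent transcripts, which start next to a coding gene's promoter and run the other way, were higher more often than lower: 109 rose and 41 fell of 301, with a median log2 fold change of 0.22 (camera, limma, adjusted p = 0.020 over 9 classes, and adjusted p = 0.035 with an estimated correlation). The 194 without coding exon overlap had a median of 0.27 (limma's camera, unadjusted p of 0.0046 with an estimated correlation), and the 107 with such overlap one of 0.15 (unadjusted p of 0.095), which was not called. The difference between them was not tested. With 10 splits of the 6 libraries chance cannot be tested at 0.05: 2 splits, the real one included, gave a preset p as small (0.0022 in the real split, 0.0020 in the other). With an estimated correlation the camera p was 0.0039 in the real split and at least 0.24 in the others. Those others hold part of the real difference as spread, so they are no measure of chance. The 4 genes over 18S ribosomal RNA genes held 0.868 ± 0.081% of counts in siCtrl and 0.963 ± 0.062% in siSFPQ (SD, n = 3; exact permutation test, two-sided, p = 0.3, where 0.1 is the smallest possible). Most of these counts were those of ENSG00000281383, over an 18S pseudogene, at 7900 ± 674 and 8349 ± 514 CPM, which was not called (edgeR, adjusted p = 0.091). ENSG00000281181, another of the 4, was called higher, at 1077 ± 145 and 1183 ± 80.3 CPM (edgeR, adjusted p = 0.018). ENSG00000280441, not among the 4, has a listed span (chromosome 21, 8380643 to 8454792) that holds the position of ENSG00000281181. It was called lower, at 59.6 ± 6.61 and 42.6 ± 5.99 CPM (edgeR, adjusted p = 0.0028).

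The rise of snoRNA host genes was weighed against technical explanations. The 11 hosts without overlap by GENCODE 29 exons had a median of 0.52 (limma's camera, p = 0.040 with an estimated correlation). The counted exons can differ from that release, where only 6538 of the 13886 shared genes had an identical start and end. SNHG8, among the 11, had a listed exonic length of 6855 over a span of 1363. Reads of coding exons as the whole cause are therefore argued against only so far as the exons match. The list's lowest median was 0.38 under RLE, upper-quartile and plain scaling. Over these scalings the median of all tested genes ran only from 0.00042 to 0.072, so they could hardly move the list. The choice among them does not account for the rise, but they cannot see a shift common to all genes. A trend with exonic length and level is argued against by a median of 0.50 after its removal. Also open is a rise shared with ribosomal protein genes, which like many snoRNA hosts begin with a terminal oligopyrimidine tract. Genes over their exons had a median of 0.19 (camera p = 0.00013, but p = 0.17 with an estimated correlation). No biological explanation was tested further, and the knockdown itself was not checked on SFPQ.

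Genes inside long coding genes were tested because SFPQ has been tied to transcription of long genes. All libraries were treated with an inhibitor of transcription and none was left untreated. Neither this test nor the comparison by gene length can therefore tell transcription from other sources of RNA level. Those inside coding genes of over 100 kb differed from those inside shorter ones by -0.034 in median log2 fold change. The camera test of limma across genes gave an unadjusted p of 0.60, so the pattern itself was not established. The difference was -0.064 after removing a trend with exonic length and level, and 0.15 among genes without coding exon overlap. With no established pattern, neither value bears on a source.

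Other splits of the 6 libraries number 10 with the real one, too few for a share under 0.05. Each of the 9 others sets 2 libraries of one siRNA and 1 of the other against the reverse, so it keeps part of any real difference, holds the rest as spread, and gives no measure of how often calls arise without a difference. The real split called 3063 genes and the highest other 0, and 1 split reached the real number. For the fixed lists at the preset correlation the real split called 1 and the highest other 1, and 8 splits reached the real number. For the coding-locus groups at the preset correlation the real split called 7 and the highest other 2, and 1 split reached the real number. With an estimated correlation the real split called 0 coding-locus groups and 1 fixed list, the snoRNA host genes (camera adjusted p = 0.026). In the other splits that correlation called 0 fixed lists, with a smallest camera adjusted p = 0.43 for the snoRNA host genes.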
